A study of Mus musculus with 6 samples.

How the data were processed

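RNA was measured in 6 libraries from extraembryonic ectoderm, the trophoblast tissue next to the epiblast, of mouse embryos at embryonic day 7.5. The embryos were of the B6D2F1 strain and were made by in vitro fertilisation (IVF). Per the labels, 3 libraries came from IVF embryos injected with water (IVF control) and 3 from IVF embryos injected with a short interfering RNA against Kmt2e (siKmt2e). The labels' protocols describe collection of trypsin-digested cells, oligo(dT) priming, template switching in the manner of Smart-seq2, sonication of the cDNA and a ligation library kit. They do not give the number of cells or embryos behind a library, the stage of injection or the dose. Nothing says that the replicates came from separate embryos, so p-values measure only the spread between these samples, which may be technical.

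Per the submitters' processing notes, CASAVA, HISAT2 2.1.0, featureCounts 1.6.1 and edgeR were used with the mm9 genome build. The roles of these tools, their settings and the handling of strand are not given in the sources used here. The authors deposited whole-number counts per gene, not normalised, with each gene's position and exon length, per the file headers. The authors also deposited a table of log2 values for 15791 genes, which equalled log2(CPM + 1) of the counts to within 4.999e-06, where CPM is the count as a share of the library total on its usual scale. The 8600 genes outside that table had no count in any library. The count table held 24391 genes, of which 10446 had no count in any library, and no gene of the mitochondrial genome. Coordinates are those of the count table. A reference of another build was not used for coordinates.

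Total counts per library were 21108188, 17138175 and 19815177 in IVF control and 13307285, 13560904 and 16776151 in siKmt2e. Without molecular identifiers, reads are not independent molecules, so intervals and floors from counts cover counting error only. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom lay between 119 and 272. Even counts were in excess in every library, as they would be if both mates of a pair had been counted. Among genes with 100 to 999 counts, 72.5% ± 0.263 of the counts were even in IVF control and 77.4% ± 0.0402 in siKmt2e (SD, n = 3 each). Counts of antisense or overlapping genes cannot be told apart without strand, and this limit is given beside the genes it touches.

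The comparison used edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 10336. Library totals were scaled by trimmed mean of M-values (TMM), and groups were compared by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) are the log2 fold change divided by the square root of F. CPM values in the text use the TMM-scaled totals and are given as mean ± SD with n = 3. A fold against a group with no count is a bound against 3 counts over that group. Gene lists were compared with all other genes by camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes, for lists with at least 5 tested members, with adjustment over the 24 lists tested. Camera was repeated with an estimated correlation, and fry was run as another test. The test was tried on simulated counts with 200 changed genes among 9786 tested: it made 72 calls, of which 5.56% were false, and recovered 7.46%, 38.8% and 56.1% of genes changed 2-fold, 4-fold and 8-fold. On the same simulated counts, 63.9% of the calls of DESeq2 1.42.0 and none of those of limma-voom were false. The simulated genes were drawn independently and without a trend by gene length, so these shares need not hold for the real calls.

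The comparison, the alternatives, 31 gene lists and the rule for named genes were fixed before the data were examined. Of the 475 symbols in the lists, 462 were found in the table. The rule named Kmt2e, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose mean count was at least 20 in the higher group, and up to 4 members per list past the threshold. Where fewer than 2 members of a list passed, those with the highest mean CPM were added up to 2. Gene models without a name were counted only. Single values per library were compared by two-sided exact permutation tests, whose smallest possible p with 3 against 3 is 0.1.

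Alternatives were DESeq2 size factors, library totals and upper-quartile scaling; no filter and a filter of at least 5 CPM in 3 libraries; a replicate block; leaving out each library; limma-voom, the older quasi-likelihood method and DESeq2; limma on log2(CPM + 1) and log2(CPM + 0.1); and a 2-fold limit. After the data were seen, further alternatives were added: counts rounded up after division by 2, the 45S ribosomal RNA gene left out, counts thinned to the smallest total, and offsets corrected for gene length. The length correction took each library's log2 deviation from the mean of all libraries and fitted it smoothly against log2 exon length over the better-expressed genes, either over all such genes or over those in no list. Values given as length-corrected use the latter. The exon length is that of all annotated exons of a gene together, which can exceed the length of the transcript in these cells. Then 5 lists were added after the data were seen, and they are reported only under other observations.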

Results

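The transcriptome of extraembryonic ectoderm was measured at embryonic day 7.5 in 3 libraries of water-injected IVF embryos and 3 libraries of Kmt2e siRNA-injected IVF embryos. Kmt2e encodes a SET and PHD domain protein of the KMT2 family. According to the series' design text, the comparison asks whether interference with Kmt2e alters the extra-embryonic gene expression of IVF embryos. Embryos from natural fertilisation were not analysed here, so the comparison holds IVF control against siKmt2e alone. Library totals ran from 13307285 to 21108188 counts and were lower in siKmt2e (mean 14548113 against 19353847, exact permutation p = 0.1, the smallest possible). The number of genes detected was 10871 ± 96.6 in IVF control and 10531 ± 158 in siKmt2e (SD, n = 3 each). The first principal component of log2 CPM held 27.3% of the variance and separated the groups. Across genes, which are not independent replicates, Spearman's rho was 0.845 to 0.855 within IVF control, 0.829 to 0.836 within siKmt2e and 0.796 to 0.817 between groups.

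Kmt2e itself (chromosome 5, 22940247 to 23010047, plus strand, mm9) had 58.0 ± 30.7 CPM in IVF control and 42.8 ± 10.2 CPM in siKmt2e. The values were 24.5, 85.0 and 64.4 CPM in the IVF control libraries and 39.5, 54.2 and 34.7 CPM in the siKmt2e libraries, so the groups overlapped. The log2 fold change was -0.42 (SE 0.51, edgeR adjusted p = 0.717), with a 95% interval from -1.51 to 0.68. That interval allows a level in siKmt2e between 35.0% and 160% of the control. A fall of the target's mRNA was therefore not detected. A level under 35.0% lies outside the interval, while a smaller fall is neither shown nor excluded. With the length correction its log2 fold change was -0.02 (adjusted p = 0.989), and without IVF_control replicate 2, the library with the highest value, it was -0.07. An exon of Kmt2e overlaps Srpk2 on the opposite strand, and the reads of the 2 genes in that part cannot be told apart.

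Between the groups, 396 of 10336 tested genes changed, 204 higher and 192 lower in siKmt2e. Trophoblast regulators were among the genes that rose: Tfap2c, a transcription factor of trophoblast, went from 57.5 ± 20.0 to 237 ± 15.4 CPM, and Ascl2, a transcription factor of the spongiotrophoblast lineage, from 9.32 ± 7.37 to 74.9 ± 29.1 CPM. Embryonic globin and erythroid regulator transcripts appeared in siKmt2e, with Hbb-bh1 at 44.4 ± 10.5 CPM against no count in any control library. Slc2a3, the neuronal-type glucose transporter GLUT3, which is also abundant in trophoblast, fell from 13045 ± 720 to 4492 ± 292 CPM. The endocytic receptor component Amn and the iron carrier Trf, both made in visceral endoderm, fell as well.

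All 396 called genes had groups that did not overlap; among all tested genes 2457, or 23.8%, did not overlap, where chance gives 10%. At an unadjusted p under 0.05 there were 1989 genes, and 199 of the called genes had a fitted change of at least 2-fold. The difference between groups followed gene length. In genes of no list, the median log2 fold change was 0.54 for 364 genes with up to 750 bases of exon and fell in each longer class, to -0.39 for 1218 genes of over 6000 bases. In every library the same contrast held: short minus long genes deviated by -0.44, -0.64 and -0.51 in IVF control and by 0.38, 0.37 and 0.42 in siKmt2e (log2 CPM, short being up to 1000 bases). With length-corrected offsets 188 genes were called, of which 152 were shared with the 396. Leaving out a single library lowered the count to 199, 220 and 266 (IVF_control replicates 1, 2 and 3) and to 201, 164 and 149 (siKmt2e replicates 1, 2 and 3). The calls kept through all 6 of these fits numbered 112, and 73 of them also kept their call and direction with the length correction.

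**Figure D1:**
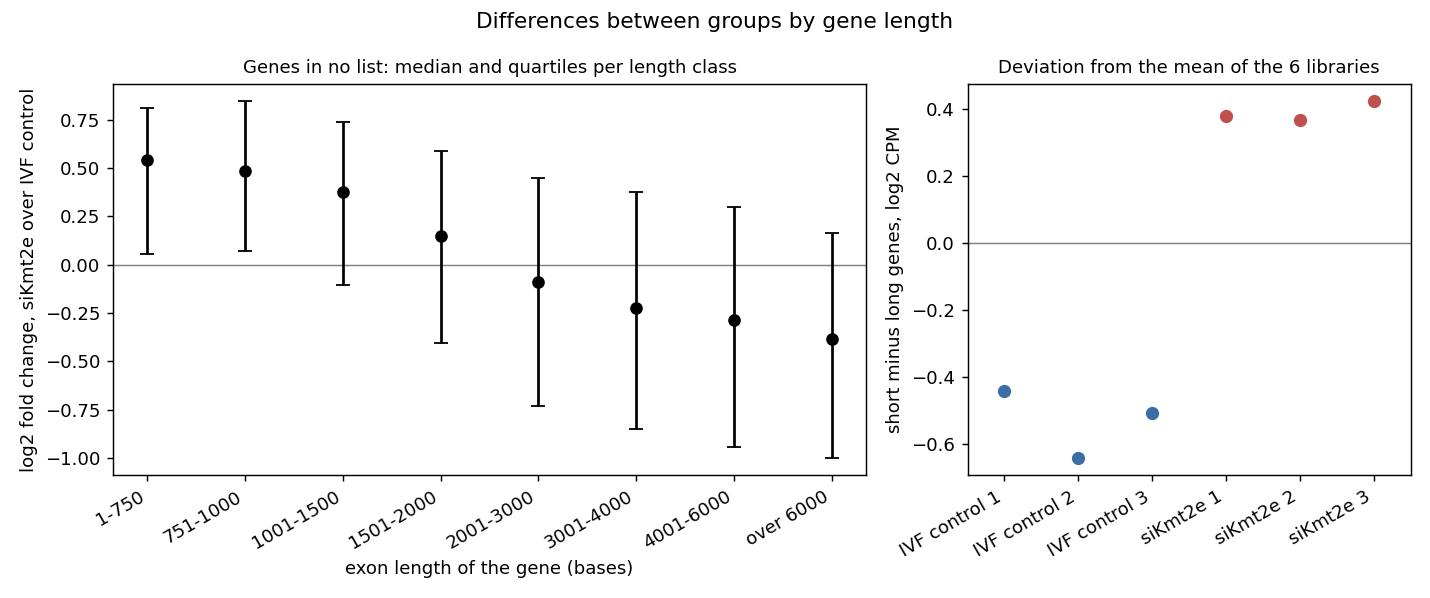
Left, median log2 fold change (siKmt2e over IVF control, points) and quartiles (whiskers) of genes in no list, by exon length class in bases. The median falls from 0.54 to -0.39. Right, for each library, the median deviation from the mean of the 6 libraries of genes of up to 1000 bases minus that of genes over 6000 bases, in log2 CPM; the 3 IVF control libraries lie below 0 and the 3 siKmt2e libraries above.

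Of the 20 measured markers of extraembryonic ectoderm and trophoblast stem cells, 3 rose, none fell and 17 did not pass; adjusted over the list alone 4 rose. Tfap2c (chromosome 2, 172375093 to 172384121) rose by 2.04 on the log2 scale (SE 0.28, adjusted p = 0.00196). Ddah1, an enzyme of dimethylarginine breakdown (chromosome 3, 145421656 to 145557241), went from 410 ± 29.4 to 856 ± 67.5 CPM, and Id2, an inhibitor of helix-loop-helix factors (chromosome 12, 25778664 to 25780957), from 489 ± 53.7 to 942 ± 17.8 CPM. The list as a whole did not pass camera (adjusted p = 0.0893; unadjusted p = 0.0791 with an estimated correlation), but did with the length correction (adjusted p = 0.0471; adjusted p = 0.257 with an estimated correlation). In the ectoplacental cone and spongiotrophoblast list 3 of 9 rose and none fell; adjusted over the list alone 3 rose and 1 fell. Phlda2, an imprinted gene that restrains placental growth (chromosome 7, 150687453 to 150688429), went from 799 ± 125 to 1998 ± 191 CPM (log2 1.32, SE 0.12, adjusted p = 0.000122). Gjb3, a connexin, and Ascl2 rose by 1.51 (SE 0.27) and 2.97 (SE 0.61). All 6 of these genes kept their call with the length correction, with Phlda2 at 0.77 and Id2 at 0.63. Ascl2 lost its call without IVF_control replicate 2 or 3 and without siKmt2e replicate 1 or 3. In the labyrinth and syncytiotrophoblast list, Slc16a1, the lactate carrier MCT1, fell from 1444 ± 119 to 736 ± 61.5 CPM and Epcam rose from 257 ± 4.36 to 428 ± 44.5 CPM; the other 7 did not pass. Adjusted over the list alone, 1 of the 9 rose and 2 fell. Of the trophoblast giant cell markers only 3 were measured and none passed: Hand1 had a log2 fold change of 0.79 (SE 0.42) and Gata2 of 1.08 (SE 0.42).

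**Figure D2:**
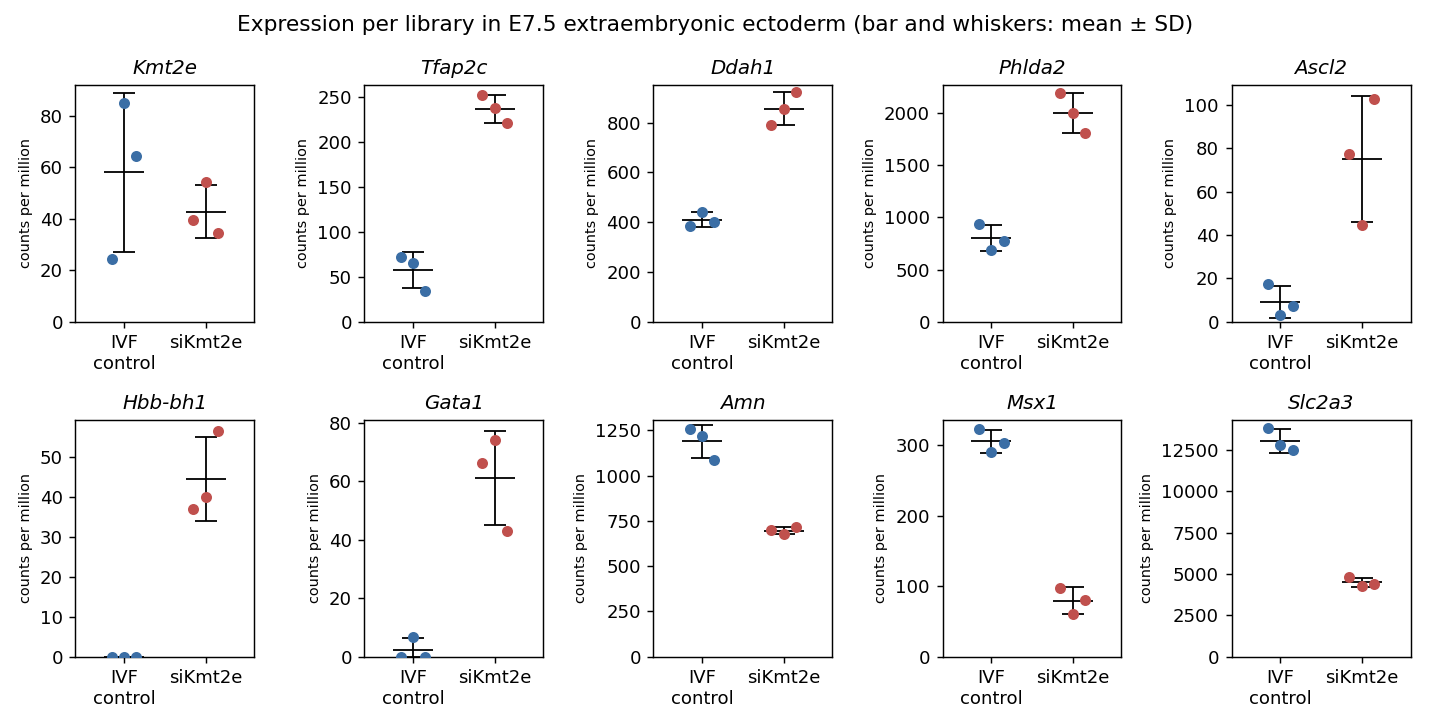
Expression in CPM (vertical axes, from 0) of 10 genes in the 3 IVF control (blue) and 3 siKmt2e (red) libraries, with mean ± SD. Kmt2e overlaps between groups; Tfap2c, Ddah1, Phlda2, Ascl2, Hbb-bh1 and Gata1 are higher and Amn, Msx1 and Slc2a3 lower in all 3 siKmt2e libraries.

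In the list of primitive and maternal erythroid genes, 4 of 5 rose, and all 5 when adjusted over the list alone (camera adjusted p = 3.34e-10; adjusted p = 0.0555 with an estimated correlation). Hbb-bh1 and Hba-x, embryonic globins, and Klf1, an erythroid transcription factor, had no count in IVF control and were at least 874-fold, 789-fold and 642-fold higher in siKmt2e (437-fold, 394-fold and 321-fold if both mates of a pair were counted). Gata1, the erythroid and megakaryocyte transcription factor, went from 2.28 ± 3.95 to 61.1 ± 16.1 CPM and kept its call without any single library. Hbb-bh1 lost its call without siKmt2e replicate 3, Hba-x without any of the siKmt2e libraries and Klf1 without any of the 6 libraries; all 4 kept it with the length correction. The list's median log2 fold change was 9.33 with genes absent from control at their bound (8.33 if both mates were counted). The extraembryonic mesoderm list stood higher as a list (adjusted p = 0.00169; 0.151 as adjusted p with an estimated correlation), although only Lmo2, a haematopoietic transcription factor, passed among its 11 members, and 2 adjusted over the list alone. Ahnak, an abundant member, had a log2 fold change of 0.38 (SE 0.37). Lmo2 had 8 counts in the control libraries together and was 225-fold higher, and with the length correction its log2 fold change was 7.77 against 7.84 (adjusted p = 0.0645).

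The visceral endoderm list stood lower as a list (camera adjusted p = 0.00342; adjusted p = 0.151 with an estimated correlation; adjusted p = 6.36e-05 with the length correction, or adjusted p = 0.0873 with both). Of its 18 genes 2 fell, none rose and 16 did not pass; adjusted over the list alone 7 fell, and with the length correction 4 fell. Amn, the partner of cubilin (chromosome 12, 112509322 to 112514637), went from 1189 ± 90.1 to 696 ± 19.4 CPM (log2 -0.77, SE 0.11), and Trf, transferrin (chromosome 9, 103111206 to 103132616), from 589 ± 176 to 251 ± 17.5 CPM (log2 -1.22, SE 0.21). Of the 10 parietal endoderm genes, Sparc (-0.72, SE 0.15) and the basement membrane collagen Col4a1 (-0.84, SE 0.21) fell, and 3 fell adjusted over the list alone. Neither passed with the length correction (-0.60 and -0.48), and camera gave the list an adjusted p of 0.0540. Among 5 epiblast genes Utf1, a chromatin factor of pluripotent cells, went from 47.7 ± 5.66 to 162 ± 16.1 CPM, while Dnmt3b had a log2 fold change of -0.20 (SE 0.18); 1 rose adjusted over the list alone. Among 7 primitive streak and nascent mesoderm genes Mixl1 fell from 39.3 ± 17.6 to 5.25 ± 2.64 CPM, also adjusted over the list alone, and Fgf3 had 0.56 (SE 0.84). Mixl1 lost its call with the length correction (adjusted p = 0.0660), under which its log2 fold change was -2.89 against -2.94. The streak list had adjusted p = 0.0893, or 0.0471 with the length correction; with an estimated correlation these were 0.271 and 0.257. Of 4 maternal decidua genes none passed: Bmp2 had -0.59 (SE 0.91), and Des, which overlaps Gm15179, had no count in control and 12.8 ± 5.14 CPM in siKmt2e. The single measured leukocyte gene, Laptm5, did not pass, and neither did any of 4 sex-linked genes; Xist had 57.1 ± 23.7 and 150 ± 44.1 CPM and Ddx3y 64.5 ± 33.8 and 41.0 ± 19.4 CPM. With the length correction Xist passed (log2 2.00, adjusted p = 0.00873), and so did 4 other list members, chosen after their values were seen: Ttr, Apom, Igf2 (which overlaps Igf2os) and Birc5 (-0.74, -0.76, 0.87 and 0.78). Adjusted over the list alone, Xist rose in the sex-linked list and 1 decidua gene rose. Xist overlaps its antisense partner Tsix.

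Among 21 writers and erasers of histone H3 lysine 4 methylation, 2 fell and none rose, and 3 fell adjusted over the list alone. Kmt2d, a methyltransferase, went from 828 ± 42.5 to 466 ± 152 CPM (log2 -0.84, SE 0.18) and Kdm5a, a demethylase that overlaps Ccdc77 on the opposite strand, from 340 ± 64.8 to 184 ± 40.9 CPM. Both are long genes, and with the length correction their log2 fold changes were -0.18 (SE 0.22) and -0.39 (SE 0.23), neither past the threshold. None of 19 genes of repressive chromatin and DNA methylation passed in edgeR or adjusted over the list alone; Kdm6b had -0.13 (SE 0.19) and Ezh2 -0.40 (SE 0.19). Of 17 imprinted genes expressed from the paternal allele, Mest rose (58.1 ± 8.07 to 143 ± 15.6 CPM) and Impact, Peg3 and Kcnq1ot1 fell (log2 -0.93, -1.28 and -0.98); adjusted over the list alone 4 rose and 3 fell. Mest alone of these kept its call with the length correction. Impact and Peg3 then had -0.73 and -0.91, and Kcnq1ot1, at 83437 bases the longest of them, had 0.08 and so no longer the same sign. Mest, Peg3 and Kcnq1ot1 overlap antisense partners. Of 16 genes expressed from the maternal allele, Phlda2 and Ascl2 rose and Rian and Cdkn1c, a cyclin-dependent kinase inhibitor, fell (log2 -1.35 and -1.61); adjusted over the list alone 2 rose and 3 fell. With the length correction Cdkn1c had -1.66 (adjusted p = 0.0541) and Rian -1.14 (adjusted p = 0.104). None of these 4 lists passed camera, and their adjusted p lay between 0.831 and 0.899.

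In the hypoxia and glycolysis list 1 of 16 rose and 2 fell, or 2 and 3 adjusted over the list alone. Slc2a3 (chromosome 6, 122677827 to 122692763) had the smallest adjusted p of all tested genes (log2 -1.54, SE 0.07, adjusted p = 4.82e-08) and -1.30 with the length correction, and it kept its call under every alternative run. Gapdh rose (510 ± 38.2 to 852 ± 111 CPM) and the phosphofructokinase Pfkl fell (751 ± 137 to 492 ± 39.8 CPM); neither kept its call with the length correction (0.52 and -0.39). Msx1, a homeobox target of BMP signalling that overlaps Msx1os, fell from 306 ± 16.7 to 79.5 ± 18.6 CPM (log2 -1.95, SE 0.24) and kept its call with the length correction; it was the only one of 9 BMP and SMAD targets to pass, by either adjustment, and Id3 had -0.00 (SE 0.25). Of 11 FGF and ERK targets Dusp6 fell (-1.45, SE 0.37; -1.30 with the length correction, adjusted p = 0.101), Spry2 had -0.19 (SE 0.22), and 4 fell adjusted over the list alone. Bax, a mediator of apoptosis, rose by 0.87 (SE 0.22) as the 1 of 9 p53 targets to pass by either adjustment, and had 0.39 with the length correction; Aen had -0.34 (SE 0.37).

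No gene passed among 24 cell cycle genes (Ccnb1 0.24, SE 0.16; Rrm2 0.18, SE 0.14), although 18 had positive values and the list passed camera with the length correction (adjusted p = 0.00659, against 0.0930 without; with an estimated correlation adjusted p = 0.134 and 0.271). None passed among 14 immediate early and heat shock genes (Hspa8 0.28, SE 0.07; Dnajb1 -0.29, SE 0.19) or 9 genes of the integrated stress response (Phgdh -0.45, SE 0.17; Psat1 -0.15, SE 0.19). The same was true of 18 genes of cholesterol synthesis (Insig1 0.47, SE 0.31; Hmgcr -0.07, SE 0.37) and 10 genes of adhesion and matrix remodelling (Itgb1 -0.09, SE 0.28; Fn1 -0.90, SE 0.32). It was also true of 8 angiogenesis genes (Flt1 -0.49, SE 0.53; Nrp1, which overlaps Mir1903, 0.11, SE 0.68), 4 interferon response genes (Bst2 0.45, SE 0.61; Ddx58 -2.01, SE 1.11) and 5 germline genes (Ddx4 -0.32, SE 0.88; Stk31, no count in control and 8.79 ± 6.73 CPM). Adjusted over the list alone, 1 heat shock gene rose, and 1 adhesion gene rose and 2 fell; the other lists of these had none. In the adhesion list the median was 0.24 and the mean -0.20, and in the angiogenesis list they were -0.48 and 0.40. Over the 13 lists with measured genes and no call in edgeR, 24 of 123 genes had an unadjusted p under 0.05, DESeq2 called 11 and limma-voom 1. Among all 10336 tested genes these numbers were 1989, 1238 and 284, so the share with an unadjusted p under 0.05 was similar. No gene of the 2-cell stage list or of the mitochondrial genome reached the test.

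**Figure D3:**
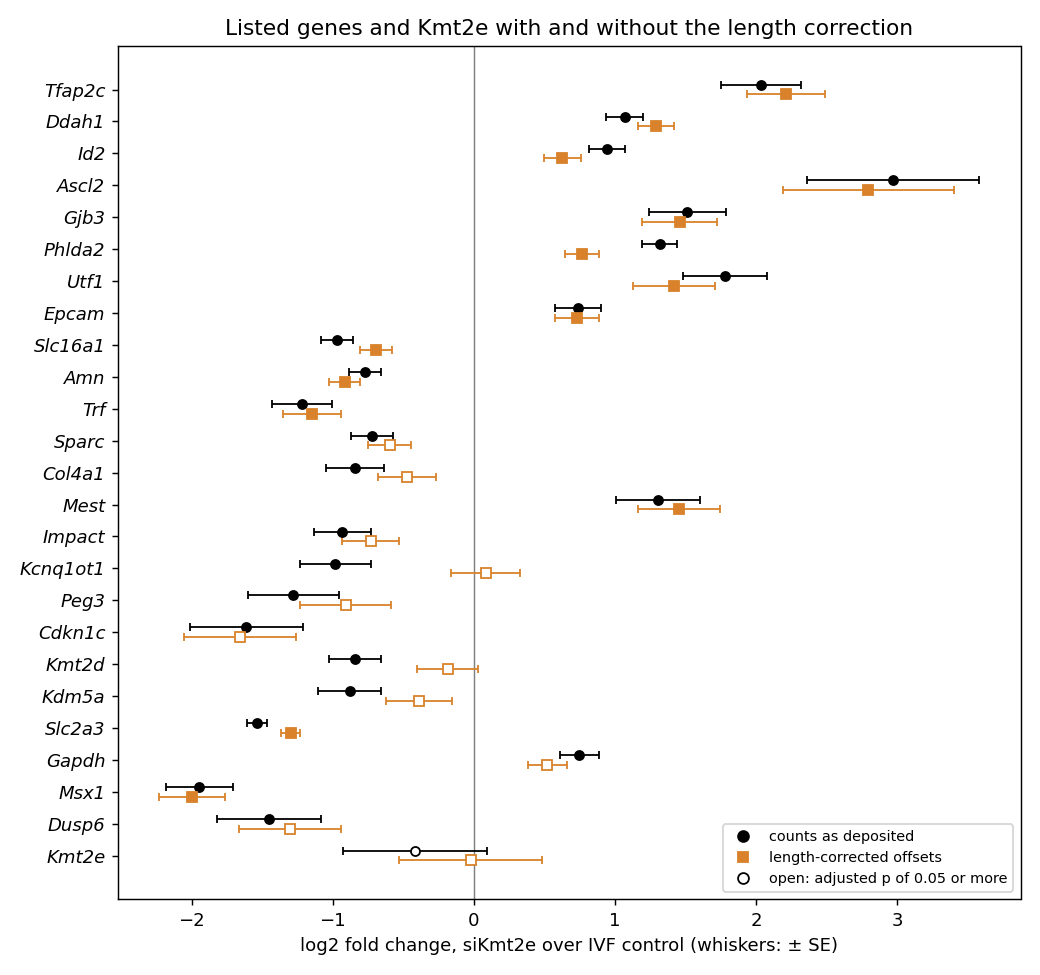
Log2 fold change (siKmt2e over IVF control, horizontal axis, whiskers ± SE) of 24 list members past the threshold and of Kmt2e, from counts as deposited (black circles) and with length-corrected offsets (orange squares); open symbols have an adjusted p of 0.05 or more. Tfap2c stays at 2.04 and 2.22, while Kmt2d moves from -0.84 to -0.18 and Kcnq1ot1 from -0.98 to 0.08.

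The largest rises were mostly of genes near absence in control. Besides the globins and Klf1, St6galnac4 had no control count and was at least 536-fold higher (268-fold if both mates were counted). Irx4 had 2 control counts and a ratio of 622, with a 95% counting interval from 195 to 5845, or from 126 to 27976 if both mates were counted. Gmip, Trp53inp2, Capg, Pcnxl4 and Dpp8 were 281-fold, 52.4-fold, 16.1-fold, 14.2-fold and 8.68-fold higher, each at 26.4 to 44.9 CPM in siKmt2e. Among the falls Efna5, the ephrin A5 ligand, had 102 ± 4.97 CPM in control and no count in siKmt2e, at least 1452-fold lower, and Zfp942 was at least 579-fold lower (726-fold and 290-fold if both mates were counted). Stoml1, Palb2, Phf6, Dock11 and Adam9 were 46.1-fold, 25.1-fold, 16.3-fold, 13.6-fold and 11.3-fold lower. Tmco3, which overlaps Dcun1d2, Slc18a2, Abcc2, Plod1 and Acnat1 were 10.4-fold, 9.56-fold, 9.36-fold, 8.70-fold and 8.58-fold lower. The measured folds are ratios of group means, and for some genes the lower mean came mostly from 1 library. In siKmt2e, Acnat1 had 0, 37.2 and 0 CPM and Dock11 0, 0.454 and 19.5 CPM. In IVF control, Capg had 8.25, 0 and 0.0990 CPM and Trp53inp2 0, 1.94 and 0 CPM. For these genes the fold is not an even change across libraries. Others were more even, such as Palb2 in siKmt2e (1.38, 1.21 and 0.920 CPM). Of these 12 rises, 8 kept their call with the length correction and 1, Gata1, kept it without each single library; of the 12 falls, 4 did and 1, Efna5, did. The 4 rises and 8 falls that lost their call with the length correction still had 98.6% to 101% and 89.5% to 99.4% of their log2 fold change.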

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

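Halved counts, the 45S ribosomal RNA gene left out, the 2 length corrections and thinned counts were chosen after the data were seen; the other alternatives were planned. The count of changed genes, 396, lay between 284 and 465 with other scalings, no filter, the 5 CPM filter, limma-voom, limma on log2(CPM + 1) or log2(CPM + 0.1), halved counts, no 45S gene and thinned counts. Leaving out single libraries gave 149 to 266 changed genes, 79 to 141 higher and 70 to 125 lower, with 3 to 5 lists past the threshold; fewer samples were fitted there, and the fit without IVF_control replicate 3 alone stayed within 1.5 times of 396. Other counts were 244 changed and 91 lower with the older quasi-likelihood method, 110 lower with limma-voom, and 199 changed, 75 higher and 124 lower with the 2-fold limit, which removes smaller changes by construction. DESeq2 gave 1238, 627 and 611, and limma on log2(CPM + 1) without a filter 60, 26 and 34 for changed, higher and lower genes. For limma the cause was not tested. On the simulated counts DESeq2 made 255 calls, of which 63.9% were false, against 72 and 5.56% for edgeR. By the simulation, its larger count may thus hold more false calls. In the other splits of the 6 libraries it called up to 88 genes where edgeR called 0. Those splits mix the groups on both sides, so calls there are not known to be false. The length correction gave 188, 108 and 80, or 185, 106 and 79 with the trend fitted over all genes, and removes by construction what follows the trend. That does not explain every lost call. Among the largest changes, the 4 rises and 8 falls that lost theirs kept 98.6% to 101% and 89.5% to 99.4% of their log2 fold change.

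A block on the replicate number gave 206 changed genes, 115 higher and 91 lower. The numbers did not pair the samples: correlations between libraries of the same number, after removal of group means, were 0.0218, -0.000151 and -0.0252. The block therefore used up degrees of freedom without a pairing to remove.

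Lists past the threshold numbered 3, and 5 with the 5 CPM filter, 4 with thinned counts, 6 with limma-voom, 6 with either length correction, 10 with fry and 0 with camera under an estimated correlation, where 0 of 24 adjusted p lay under 0.05 and the smallest was 0.0555. The 3 lists kept their direction and their call under every other alternative run on lists. Kmt2e was not past the threshold in any alternative, with log2 fold changes from -0.80 to -0.02 and adjusted p from 0.382 to 1.

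Of the 65 named genes past the threshold, 23 kept their call in all 6 fits that left out a library and 35 with the length correction. Kcnq1ot1 was the only 1 of them to change sign in any alternative: 0.0839 with the length correction, whose trend explains it by construction. The other genes that changed sign had not passed. With the length correction these were Dnmt3b 0.0640 (0.0622 with the trend over all genes), Kdm6b 0.24, Bst2 -0.0811 (-0.11), Hmgcr 0.21 and Itgb1 0.16. For the rest the cause was not tested: Id3 was 0.0265 with upper-quartile scaling, and Fgf3 was -1.06 and Ddx4 0.30 with limma-voom. Fgf3 was also -0.45 with limma on log2(CPM + 1), with or without a filter, and -1.11 on log2(CPM + 0.1). The mean shift of the epiblast list was 1.07 and -0.36 without a filter. Over the fits that left out a library, the ranges were -0.69 to 1.90 for this shift, -0.17 to 0.17 for Id3, -1.28 to 0.12 for Bmp2, -1.11 to 0.89 for Laptm5, -0.32 to 0.0619 for Kdm6b, -0.19 to 0.78 for Nrp1, -0.24 to 0.20 for Hmgcr, -0.88 to 0.80 for Ddx4, -0.31 to 0.10 for Itgb1 and -0.0752 to 1.08 for Fgf3. At this depth and with 3 libraries per group, the simulation recovered 7.46% of genes changed 2-fold and 56.1% of those changed 8-fold.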

Other observations

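Of the tests below, those of library preparation, of length for the blood genes, and of the share of cells and length for visceral endoderm were chosen only after the result was seen, as were the genes of the next paragraph and the 5 added lists.

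Among the 396 changed genes, 67 kept their call and direction without each single library, with the length correction, and with limma-voom, the older quasi-likelihood method and DESeq2; 32 of these were higher and 35 lower in siKmt2e. Lin28a, an RNA-binding protein of early embryonic cells, fell from 890 ± 90.1 to 303 ± 23.9 CPM (log2 -1.56, SE 0.15). Slc13a4, a sulfate carrier, fell from 837 ± 73.8 to 292 ± 39.7 CPM. The endocytic receptor Lrp2 and its chaperone Lrpap1 fell together (-1.36, SE 0.17, and -1.25, SE 0.13; -0.78 and -1.09 with the length correction), as did the lysosomal protease Ctsb (-0.88, SE 0.08), which overlaps Fdft1 on the opposite strand. Fabp3, a fatty acid carrier, rose from 135 ± 23.7 to 424 ± 27.5 CPM, and Tmsb10, an actin-binding peptide, from 102 ± 7.54 to 326 ± 20.6 CPM. The 45S ribosomal RNA gene Rn45s held 1.52% ± 0.243 of the counts in IVF control and 4.24% ± 0.470 in siKmt2e (log2 1.55, SE 0.10).

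Of 81 cytosolic ribosomal protein genes 55 were higher in siKmt2e and 0 lower in edgeR (adjusted over the list alone 74 and 0, and by DESeq2 69 and 0), with a median log2 fold change of 0.94; without siKmt2e replicate 2 or 3 the number higher was 30. These genes are short. Genes of no list matched on exon length and expression had a median of 0.58, which left an excess of 0.36 (SE 0.0258 from resampling genes). That SE takes the genes as independent, while camera estimated a correlation of 0.263 between them, so the SE is too small. The length correction took the median from 0.94 (median SE 0.19) to 0.40 (0.18) and the calls from 55 to 6. The calls ended because the fold shrank while the spread hardly moved. How far a fold shrank followed the annotated exon length, which can exceed that of the transcript. Rpl5, at 2019 bases, went from 0.96 to 0.94, and Rps14, at 597 bases, from 0.92 to 0.29. The calls that stayed are therefore not shown to be free of the length trend. For the ribosomal protein list the unadjusted camera p with an estimated correlation went from 0.0292 to 0.0689. Adjusted over the 5 added lists it went from 0.0487 to 0.115. In the medians the length trend of other genes covers part of this rise but not the excess, which is not shown to exceed the spread between libraries. Thinning to equal library totals left a median of 0.95. Thinning in proportion keeps the expected share of such abundant genes. It therefore cannot tell whether library totals or the number of molecules captured play a part. In a list of 19 translation factors and other genes of the same mRNA class, 11 rose and none fell in edgeR, and 6 rose with the length correction. For this list the unadjusted camera p with an estimated correlation was 0.0165, and 0.0288 with the length correction. Its members with the smallest adjusted p, Gnb2l1, Npm1, Nap1l1 and Naca, are not initiation or elongation factors. The corrected values depend on annotated length too: Naca, at 7145 bases, went from 0.92 to 1.31. A joint rise of genes of this mRNA class may therefore add to the length trend. A possible difference in library preparation is confounded with the groups and cannot be told apart from such a rise. Even counts were 4.93 percentage points more frequent in siKmt2e, which by itself does not show a difference in preparation.

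The erythroid genes past the threshold reached only 32.6 to 61.1 CPM in siKmt2e, and Alas2, which overlaps Mir3620, went from 0.947 to 11.4 CPM; of the 4 calls only Gata1 held without each library, with Hbb-bh1 lost without siKmt2e replicate 3, Hba-x without any siKmt2e library and Klf1 without any of the 6. After the length correction 4 of 5 erythroid genes stayed past the threshold. Hbb-bh1, Hba-x and Klf1 did so narrowly (edgeR adjusted p = 0.0417, 0.0471 and 0.0485), so that count says little about length. Their log2 fold changes went from 12.58, 12.40 and 12.14 to 12.25, 12.07 and 12.02, and that of Gata1 from 4.88 to 4.82. The median of other genes in the shortest class was only 0.54, which argues against transcript length for these 4 genes. A candidate explanation is blood and blood-vessel precursor cells in the dissected tissue: of 13 further markers 11 had positive values with a median of 0.48, and 0 passed in edgeR (1 adjusted over the list alone), with p = 0.140 under an estimated correlation. That p met the bound set beforehand for rejecting these cells, but the bound was wrong, because 12 of the 13 markers also had counts in IVF control and a p that misses the threshold over so few low genes excludes nothing. The most abundant of these markers, Mgst3 (77.8 and 85.2 CPM), Runx1 (67.6 and 46.9 CPM) and Sox7 (38.1 and 50.8 CPM), were already present in control. In the extraembryonic mesoderm list, 9 of 11 genes had positive values. Picked from it after the values were seen, Lmo2 went from 0.140 to 31.5 CPM and Etv2 from 0.281 to 18.6 CPM (edgeR adjusted p = 0.0389 and 0.0667). Tal1 went from 0.250 to 3.80 CPM (adjusted p = 0.334). Such cells, an erythroid programme in the tissue itself and the treatment's own effect all stay open.

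The visceral endoderm list was lower in siKmt2e, but its 12 genes of at least 100 CPM did not fall by a common factor (chi-square test of heterogeneity, p = 2.46e-07 with the length correction, 3.48e-09 without; at most 0.000458 with any 1 gene and 0.000109 with any 1 library left out). The genes that fell least changed with the correction (before and after it, Rbp4 -0.09 and -0.40, Apoa1 0.03 and -0.40, Cubn -0.49 and 0.02). On both scales Rbp4 and Apoa1 moved apart from Amn (-0.77 and -0.91) and Trf (-1.22 and -1.15). The gaps exceeded the SE of these genes (0.10 to 0.21). A smaller share of cells gives a common factor only if every gene is expressed in those cells alone and evenly. Whether that holds was not tested, so the unequal falls leave a smaller share of visceral endoderm cells open. The list's median went from -0.65 to -0.73 and its adjusted camera p to 6.36e-05, so the length trend does not account for the fall. With an estimated correlation that adjusted p was 0.151 before and 0.0873 after the correction. Among 30 further genes of endocytosis and lysosome 7 fell, Lgmn, Lamp2 and Atp6ap1 among them, and 1 rose. With the length correction 6 fell. The unadjusted camera p with an estimated correlation was 0.0238, or 0.0230 with the length correction. Adjusted over the 5 added lists these were 0.0487 and 0.0719, as for the list of translation factors and other genes of their mRNA class. Endocytic and lysosomal transcripts thus fell as well. The list was chosen after the data were seen, and a smaller share of cells that express its genes would lower it too. It therefore cannot tell what underlies the pattern. For 20 genes of the COPI and COPII coats, as abundant as the lysosome genes, the unadjusted camera p with an estimated correlation was 0.415. Of these genes 1 was lower, Copg1, 9 were positive and the median was -0.18, against -0.65 for the visceral endoderm list. That p met the bound set beforehand. However, the coat list had left out Arcn1 (-1.22) and Tmed2 (-0.55, or -0.58 with the length correction, adjusted p = 0.0541). Without the correction these secretory genes fell past the threshold, so the coat list excludes nothing. A smaller share of visceral endoderm cells, a change within them, a change in other cells that express these genes, and a possible difference in library preparation stay open.

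The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05: 1 of the 10 splits, the real one, gave 396 changed genes or more, and the highest other gave 0. With the length correction the values were 188 and 0, with limma-voom 284 and 0, and with DESeq2 1238 and 88. Every other split puts libraries of both groups on each side, so a group difference adds to the spread within sides. The other splits therefore do not show what would be called without a group difference.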
